A study of Mus musculus with 4 samples.

How the data were processed

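B220 B cells of naive mice, freshly isolated from bone marrow and spleen of Mef2c knockout and C57BL/6 mice, were profiled on 4 Agilent 1-colour arrays, 1 for each combination of tissue and genotype, per the labels. RNA was extracted with a Qiagen RNeasy kit and labelled with Cy3, per the labels' protocols. The number of animals pooled for an array, their age and sex, the way B220 cells were isolated, the part of Mef2c that was deleted and the strain background of the knockout are not given in the sources used here. Groups were taken from the labels alone, and 0 columns belonged to no sample.

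The deposited scanner files hold intensity values of 1 array each, on a linear scale, made by the authors with Agilent Feature Extraction 10.5.1.1 on an array design with probes placed on mouse build mm9, per the file headers. Per the file headers, the processed intensity was corrected for background with spatial and multiplicative detrending, with surrogate values in place of very low signals, and no normalization between arrays is recorded. The deposited series matrix holds the same intensity values: each of its columns equalled the processed signal of 1 array at all 45018 spots, with a tolerance of 0. Its scale is therefore linear, without centring or direction, and its column medians were 85.4 for marrow KO, 82.7 for marrow WT, 37.9 for spleen KO and 93.0 for spleen WT. Per the file headers, both marrow arrays were on slide 1 and scan 1 and both spleen arrays on slide 2 and scan 2, with KO at position 1 and WT at position 2 of each slide.

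Of the spots, 43379 were gene spots, and control spots were left out. Between 72 and 85 gene spots per array with an outlier mark were dropped, and 0 were saturated. Signals were taken to log2, the array's 75th percentile over gene spots was subtracted, and spots of a probe were averaged (245 probes of 60 bases had 10 spots). That percentile was 520 on spleen KO and between 961 and 1008 on the other arrays. Agilent's spike-in probes had median signals of 2210 on marrow KO, 1888 on marrow WT, 1223 on spleen KO and 443 on spleen WT, and were not used for scaling. A gene was represented by its brightest probe, by the mean of 4 arrays, and 8711 genes had over 1 probe. Probes were named through the accession in the file and the reference table of build GRCm38.p6, which was used for names only: 25255 of 41174 probes were matched this way, 6239 had a file name that is a current symbol, and 9680 kept another file name. This gave 28302 genes or names. Where a gene had 2 or more measured probes, these lay over 2-fold apart for 12.5% of genes in the marrow, 49.2% in the spleen, 35.0% between the WT tissues and 22.8% between the KO tissues.

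A gene was measured in a comparison when its probe was well above background, by Feature Extraction's own mark, on at least 1 of the 2 arrays. Where it was well above on 1 array only, the difference is a lower bound against the higher of the dim probe's own value and the lowest value well above background on that array, written as at least N-fold. For 34 to 63 genes per array another probe was above background where the brightest was not. Genes at least 2-fold apart, bounds included, were counted. With 1 array per group these counts have no replicate check and no p-value. For the overlap of both tissues the number shared by independent lists was computed as the product of both counts over the genes measured in both. The correlation of differences was computed across genes.

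In all, 27 gene lists were fixed: the Mef2 family and partners, pro-B and pre-B cell genes, B-lineage transcription factors, mature B cell genes, marginal zone and B-1 genes, B cell receptor signalling, MHC class II, cell division, apoptosis, DNA repair and p53, interferon-induced genes, immediate early genes, myeloid transcription factors, markers of T, NK, neutrophil, macrophage, erythroid, plasmacytoid and conventional dendritic, plasma, platelet, progenitor, stromal and basophil cells, sex genes and control genes. A list's median difference was set beside the medians of 10000 random lists of the same size, drawn within 20 bins of mean expression, and is given as a percentile or with the range from the 2.5 to the 97.5 percentile. This describes these arrays and is not a test over animals. Medians use measured differences. For lists with members above background on 1 array only, the median was also computed with these at their bound.

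The test was limma's moderated test with tissue and genotype as terms on all 4 arrays, over 22056 genes well above background on at least 1 array, with Benjamini-Hochberg adjustment and a threshold of 0.05. It takes both tissues as repeats of 1 genotype effect, has 1 residual degree of freedom, and is not independent if both tissues came from the same animals. Whether the genotype effect differs between tissues has no residual degree of freedom and was not tested. For lists, the limma p-values were also adjusted over the list alone. Tested on simulated data with planted effects, limma recovered 0.9% of effects of log2 1, 12.6% of log2 2, 54.0% of log2 3 and 87.4% of log2 4, with 19.5% of its calls false, and it called 6.15 genes on average, from 0 to 44, where nothing was planted. Lists of 20 randomly drawn genes were tested in the marrow comparison of KO and WT, with a shift added to their measured differences. They lay outside the random range in 4.5% of cases without a shift, and in 41.5%, 96.5% and 100% with shifts of 0.25, 0.5 and 1. These rates do not carry over to the other comparisons, where random lists spread more widely. For the mature B cell list their SD was 0.08 in the marrow, 0.18 in the spleen and 0.18 between the WT tissues.

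Genes were named by a rule: Mef2c; the 10 highest and 10 lowest genes for KO against WT in each tissue and for the WT tissues, among genes above background on both arrays, at least 2-fold apart also under normexp with quantile normalization, and with a symbol that is no clone, predicted or antigen receptor segment name; the 10 per direction with the largest smaller difference of both tissues; up to 5 members per list with the largest difference; the 5 per direction with the largest difference between tissues of the KO minus WT difference; the 5 per direction with the largest bound; and the 5 per direction with the smallest limma p. Other list members and genes beside these, such as Rag1 and Il7r in the marrow, were named after their values were seen. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined, save for those named as added or as chosen after results were seen.

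RNA quality was checked with 3729 pairs of probes of the same transcript, by the difference of the 3' probe minus that of the 5' probe. The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling by the median of probes above background, the series matrix values, other filters on background, the median over a gene's probes, thresholds of 1.5-fold and 3-fold, an intensity trend with robust variance in limma, and an adjusted p under 0.1. Cyclic loess, leaving out genes whose probes differ over 2-fold and leaving out the spleen KO array were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. Immunoglobulin and T cell receptor segments, clone names and predicted genes were counted but not described one by one. Sequence variants and probe sequences were not analysed here, and a few genes that the rule names are not reported.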

Results

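RNA of B220 B cells, cells of the B lineage that carry the B220 form of the surface phosphatase CD45, was measured on 4 Agilent 1-colour arrays. The cells were freshly isolated from bone marrow and spleen of naive Mef2c knockout (KO) mice and of C57BL/6 mice (wild type, WT), with 1 array for each of the 4 groups. The labels give neither the number of animals behind an array nor their sex, so no difference within a tissue has a replicate check, and the number of arrays limits the precision. Each array held 45018 spots for 41174 gene probes. The 75th percentile of the signal was 1008 on marrow KO, 961 on marrow WT, 520 on spleen KO and 970 on spleen WT, and 70.4%, 71.98%, 59.3% and 69.1% of gene spots were well above background. Repeated spots of a probe differed by a median SD of 0.0639 to 0.0780 on the log2 scale, which covers the spotting of 1 array only. Levels below are log2 signals relative to each array's 75th percentile, and differences are log2 values for KO minus WT or spleen minus marrow.

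Mef2c, a MADS box transcription factor of lymphoid and muscle cells, was not lower on either array labelled KO by its brighter probe. This reference-transcript probe, on chromosome 13 at 83802754 to 83802813 of mouse build mm9, had signals of 5511 on marrow KO and 4218 on marrow WT, a difference of 0.32 (1.25-fold). In the spleen the signals were 11838 on KO and 8534 on WT, a difference of 1.37 (2.59-fold), which was 0.67 with quantile normalization and 0.38 with the median over both Mef2c probes. A dimmer probe from a cDNA clone, at 83717123 to 83717182, differed by 0.36 in the marrow and by -0.61 in the spleen. The labels do not state which part of the gene was deleted, and a probe outside that part says nothing about the deletion, so the genotype below is that of the labels and every direction rests on them. A list of 15 measured genes held the Mef2 family and partners, among them class IIa histone deacetylases that bind Mef2 proteins and upstream kinases. Its median was 0.07 and its mean -0.09 in the marrow, where Hdac9, one of these deacetylases, was lower by a log2 difference of -2.21. The same list had a median of 0.31 in the spleen, with Hdac7 at -2.37, and that median changed sign under quantile normalization and cyclic loess.

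The marrow comparison asked how B lineage cells of mice labelled Mef2c KO and WT differ at the site where they develop. The array labelled KO had lower levels of MHC class II and mature B cell genes and higher levels of early B cell and neutrophil genes than the WT array. Of 11 measured genes of MHC class II antigen presentation, 9 were at least 2-fold lower and 0 higher, with a median of -1.73. H2-Eb1, which encodes a class II chain, differed by -2.96, H2-Aa by -2.48, and Ciita, the master activator of class II transcription, by -2.11. Of 32 mature B cell genes 10 were at least 2-fold lower and 1 higher, with a median of -0.60. They included Fcer2a, the low-affinity IgE receptor CD23, at -3.05 (8.31-fold lower), and Cd22, an inhibitory co-receptor of the B cell receptor, at -2.43. Also lower were the chemokine receptor Ccr6 at -1.57, and the complement receptor Cr2 at -1.70. The adhesion receptor Cd44 was 1.12 higher. Both medians lay at percentile 0 of random gene lists of like expression, 95% of which lay between -0.27 and 0.28 for the class II list and between -0.15 and 0.15 for the mature B list.

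Genes of earlier stages stood higher on the marrow KO array. Of 23 pro-B and pre-B cell genes 7 were at least 2-fold higher and 1 lower, with a median of 0.62 at percentile 100 of random lists. Dntt, the template-independent DNA polymerase of antigen receptor joining, differed by 1.54, Vpreb1, part of the surrogate light chain, by 1.34, Arpp21 by 2.04 and the ETS factor Erg by 2.05. The recombinase gene Rag1 differed by only -0.07, the interleukin 7 receptor gene Il7r by -0.60 and Sox4 by -1.31. The 25 B-lineage transcription factors had a median of -0.30 at percentile 0, with 2 at least 2-fold lower, namely Pou2f2 at -1.71 and Pax5, the factor that maintains B cell identity, at -1.10, and 1 higher, Id2, an inhibitor of such factors, at 1.63. Of 29 B cell receptor signalling genes 3 were at least 2-fold lower, Cd22, the receptor subunit Cd79a at -1.87 and the kinase Blk at -1.63, with 0 higher and a median of -0.26 at percentile 0. The 17 marginal zone and B-1 genes had a median of 0.42, with 3 higher and 1 lower, Bhlhe41 at -1.08. The higher ones were the tetraspanin Cd9 at 2.70, Cd5 at 1.95 and Cd36 at 1.64. Others went both ways, such as Spn at 0.76, Mzb1 at 0.73, Dtx1 at -0.44 and Cd1d1 at -0.27. Whether B lineage cells carried these differences was not tested. None of 33 cell division genes was 2-fold apart and their median was 0.05. The 20 apoptosis genes had a median of 0.02, with the death receptor Fas at 1.93, and the 23 genes of DNA repair and p53 one of -0.17, with Trp53 at -0.83. The 28 interferon-induced genes had a median of 0.29, above the range of random lists like that of the marginal zone and B-1 genes, with 6 higher, such as Oas3 at 2.48, and 1 lower, Mx1 at -1.28. For 25 immediate early genes the median was -0.17 and the mean 0.14, with Fosl2 at 3.59.

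Markers of other cell types that a B220 isolate could hold were measured beside these groups. Of 17 neutrophil genes, 16 were at least 2-fold higher on the marrow KO array, with a median of 2.56. The collagenase gene Mmp8 differed by 4.65, the chemokine receptor Cxcr2 by 4.70, the granulocyte growth factor receptor Csf3r by 4.49 and S100a8, an abundant calcium-binding protein of neutrophils, by 2.36. Myeloid transcription factors had a median of 0.60, with 3 of 11 higher, among them Cebpd at 3.54. Platelet genes had a median of 1.35 with 7 of 12 higher (Thbs1, 3.48), stromal genes one of 1.73 with 10 of 13 higher (Pdgfra, 2.64) and progenitor genes one of 0.82 with 3 of 9 higher (Cd34, 2.27), all above the range that held 95% of random lists. Inside the range of random lists were macrophage genes (0.15, although 5 of 18 were higher, such as Itgam at 3.53), NK cell genes (0.12), conventional dendritic cell genes (0.33), basophil genes (0.31) and plasma cell genes (-0.12, with Jchain, the joining chain of secreted antibodies, at -2.54). T cell, erythroid and plasmacytoid dendritic cell genes had medians of -0.14, -0.14 and -0.00, which changed sign under cyclic loess, and means of 0.45 for T cell and 0.07 for plasmacytoid genes. Of 15 T cell genes 5 were at least 2-fold higher (Cd3d, a chain of the T cell receptor complex, 3.78) and 0 lower. The 14 control genes had a median of -0.01, which was 0.02 when arrays were scaled by a median. The 5 sex genes had a median of -0.94, with Ddx3y of the Y chromosome at -1.59 and Xist at 0.48. The other Y-linked genes, Uty, Kdm5d and Eif2s3y, differed by -1.05, -0.94 and -0.87. The sex of the animals may therefore differ between the marrow arrays.

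Over all 21229 genes measured in the marrow, 1771 were at least 2-fold higher and 1040 lower on the KO array, 13.2% in all. These counts include 289 and 265 genes that were well above background on 1 array only and counted by a lower bound. Among the highest stood Jhy, needed for motile cilia of the brain's lining, at 7.66 (202-fold higher, probe on chromosome 9 at 40703592 to 40703651), the cathepsin protease gene Ctsk at 5.53, the kallikrein Klk1b24 at 5.47 and the ectonucleotidase Nt5e (CD73) at 5.24. Csta2 (6.64), Cstdc4 (6.21) and Stfa2l1 (5.71), inhibitors of cysteine proteases, belong to a family of near-identical copies, so that which copy was measured is uncertain. Among the largest negative differences were those of Cdk5r2, an activator of the kinase Cdk5, at -3.90, Eps8l1 at -3.56, and Il4i1, a secreted amino acid oxidase, at -3.16. Zfp125 was at least 18.8-fold lower and the surface protein gene Cd109 at least 29.4-fold higher. The share of higher genes among those 2-fold apart was 63.0%, and became 75.2% with normexp background correction, 74.9% with cyclic loess, 52.0% without a filter on background and 48.7% at a threshold of 1.5-fold. The position of the KO and WT arrays on the slide was the same in both tissues, so position and genotype cannot be told apart.

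The spleen comparison asked the same of B cells at a mature site. The array labelled KO again had lower MHC class II genes, together with lower B-lineage transcription factor genes, and had higher immediate early, neutrophil and macrophage genes. Class II genes were at least 2-fold lower in 8 of 11 cases and higher in 1, the protease Ctss at 1.62, with a median of -1.14 where random lists had a median of 0.85. Ciita differed by -4.12 (17.4-fold lower), H2-DMb2 by -2.16 and H2-Aa by -1.69. Of 25 B-lineage transcription factors 11 were lower and 3 higher, with a median of -0.16 against 0.63 for random lists. Pou2f2 differed by -3.19, Id3 by -2.57, Spi1 (PU.1) by -2.32 and Bach2, a repressor of plasma cell fate, by -1.91, whereas the coactivator Pou2af1 was 2.17 higher. B cell receptor signalling genes had a median of -0.07 and a mean of 0.02, and the median was 0.025 when arrays were scaled by a median, against 0.77 for random lists. Of its 29 genes 6 were at least 2-fold higher and 4 lower, with Cd79a at -2.46, Blk at -2.31 and Fcgr2b, the inhibitory Fc receptor, at 1.98.

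Mature B cell genes in the spleen went both ways: 9 of 32 were at least 2-fold higher and 7 lower. Fcer2a was lower by a log2 difference of -3.97 (15.7-fold), Cd22 by -2.24 and the tetraspanin Cd37 by -1.69, while the costimulatory ligand Cd86 was 2.21 and Ms4a1 (CD20) 1.17 higher. The list's median of 0.24 lay below the 0.72 of random lists and changed sign under quantile normalization and cyclic loess. Of 25 immediate early genes, a list that also holds genes known to respond to the dissociation of tissue, 14 were higher and 1 lower, with a median of 1.31 at percentile 100. Hspa1a, the inducible heat shock protein 70, differed by 7.25 (153-fold), its copy Hspa1b was at least 70.9-fold higher, Dusp1 differed by 2.98 and Jun by 2.11, against -1.93 for Zfp36. Of 16 neutrophil genes 10 were higher and 1 lower, with a median of 1.16 at percentile 100. Camp, the antimicrobial peptide cathelicidin, differed by 5.31 (39.8-fold), S100a9 by 3.89 and Ltf, lactoferrin, by 3.45. Macrophage genes were higher in 10 of 18 cases (median 1.07; Marco, a scavenger receptor, 2.61), and erythroid genes in 8 of 12 (median 1.22; Alas2, the first enzyme of haem synthesis, 1.55). The 28 interferon-induced genes had a median of 0.64, with Ifit1 at 2.01 and Irf7, the inducer of type I interferon, at -2.01. Random lists held the medians of early B cell (0.44), marginal zone and B-1 (0.61), cell division (0.23), apoptosis (0.07), DNA repair and p53 (0.15), T cell (-0.34), NK cell (0.36), plasma cell (0.12) and control genes (0.33) within their range, and those of early B cell, cell division, apoptosis, DNA repair and p53, plasma cell and control genes changed sign under cyclic loess. The means of NK cell (-0.18) and plasma cell genes (-0.21) had the other sign.

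In the spleen 3923 of 19807 measured genes were at least 2-fold higher and 2863 lower on the KO array, 34.3% of genes and 2.41 times the marrow's number. The median gene differed by 0.27, with medians of 0.12, -0.06, 0.30 and 0.75 in 4 equal bins of genes from the dimmest to the brightest, and the share of higher genes was 57.8%, or 69.8% with normexp and 47.2% with the median over a gene's probes. Rgs1, a regulator of G protein signalling, differed by 4.77 and Ctse, cathepsin E, by 4.81, and Ifi202b, an interferon-induced DNA-binding protein, was at least 169-fold higher. Slc4a7 (6.46) and Col6a4 (6.49) were among the highest genes by their brightest probe, while another of their probes differed by 0.28 and -0.53. Several signs of RNA composition moved with this comparison. The ribosomal RNA probe of Rn18s differed by -7.71 and that of Rn28s1 was at least 1471-fold lower on the KO array. Over 3729 pairs of probes along the same transcript, at a median of 1156 bases from each other, 43.2% of pairs differed by over 2-fold in the spleen and 6.46% in the marrow, and the probe nearer the 3' end was higher than the other by a median of 0.53 and 0.15. Of the 4 measured Y-linked genes 4 were well above background on both marrow arrays and on spleen WT, and 0 on spleen KO, where Ddx3y was at least 37.8-fold lower. The marrow comparison uses the spleen KO array only in choosing each gene's probe. With that choice made over the other arrays, 1773 genes were higher and 1047 lower on marrow KO.

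**Figure D1:**
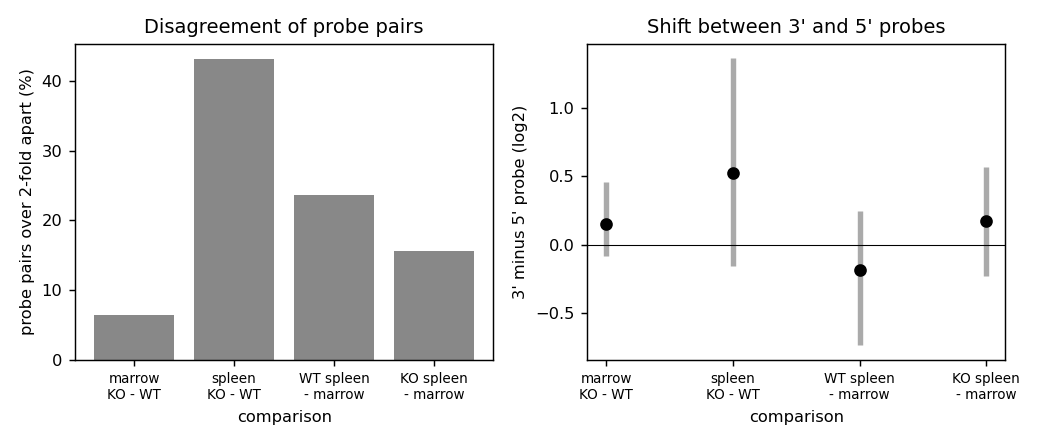
Bars give the percentage of 3729 probe pairs of the same transcript whose log2 differences lay over 2-fold apart in each of the 4 comparisons, and points the median difference of the 3' probe minus the 5' probe (log2) with its interquartile range as a line. Spleen KO against WT stood highest in both, at 43.2% and 0.53, against 6.46% and 0.15 in the marrow.

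Both tissues together were compared for genes that differed the same way. Of 18979 genes measured in both, 441 were at least 2-fold higher in KO in both tissues, where independent lists would share 259, and 386 were lower in both, where independent lists would share 119. Opposite directions were found for 79 genes higher in marrow and lower in spleen (182 for independent lists) and 39 the other way (170). Shared higher genes included Ctse (4.52 in marrow, 4.81 in spleen), the serine protease Prss23 (3.93, 3.51), Mmp8 (4.65, 3.36) and Il1r2, the decoy receptor of interleukin 1 (3.87, 3.21). Shared lower genes included Fcer2a (-3.05, -3.97), Il4i1 (-3.16, -2.49), Cd22 (-2.43, -2.24) and Jchain (-2.54, -2.24), and with them Rn18s (-2.43, -7.71) and Lars2, the mitochondrial leucine tRNA synthetase (-3.05, -4.99). Across 16511 genes above background on all 4 arrays the KO minus WT differences of both tissues had a Pearson correlation of 0.34 and a Spearman correlation of 0.39, across genes, which are not independent replicates.

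**Figure D2:**
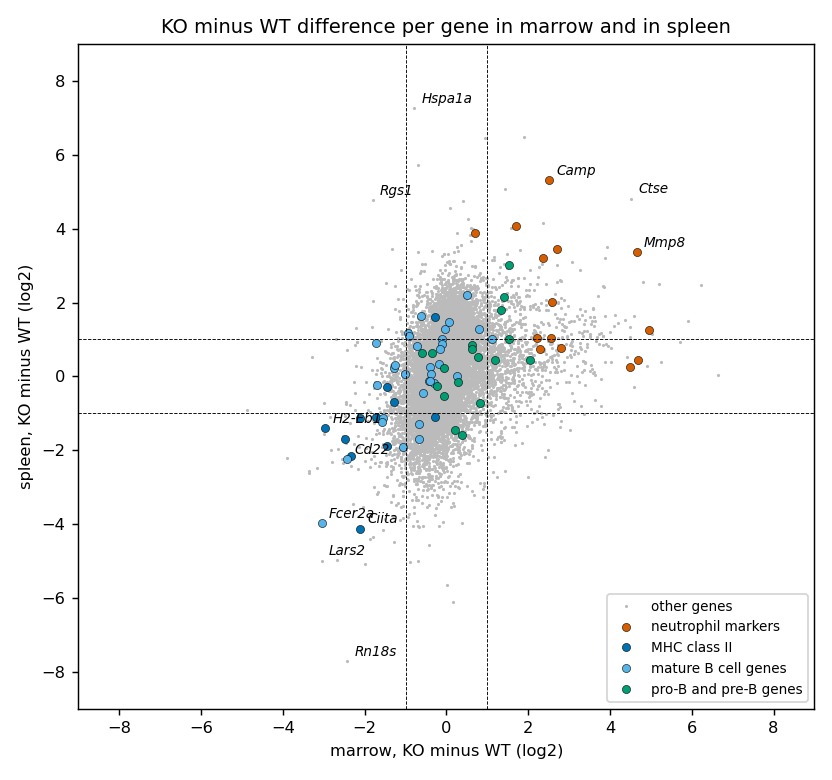
Each point is 1 of 16511 genes above background on all 4 arrays, with its KO minus WT difference (log2) in marrow on the x axis and in spleen on the y axis; dashed lines mark 2-fold, and colours mark neutrophil, MHC class II, mature B cell and pro-B and pre-B cell genes. Most MHC class II genes (list medians -1.73 and -1.14) lie at the lower left, except Ctss (-0.29 and 1.62), and the neutrophil genes shown (list medians 2.56 and 1.16) lie at the upper right.

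The only test that the 4 arrays allow takes both tissues as repeats of 1 genotype effect. In limma, 8 genes were higher and 2 lower in KO at an adjusted p under 0.05 among 22056 genes, and 2500 had an unadjusted p under that level. Jhy rose by 8.27 (SE 0.568, adjusted p 0.000564 in limma), Klk1b24 by 5.96 (SE 0.557, adjusted p 0.00595), the arginase gene Arg2 by 5.20 (SE 0.560, adjusted p 0.0155) and Ctse by 4.66 (SE 0.538, adjusted p 0.0183), each higher in both tissues. Sema3a, a secreted axon guidance protein, and Ccr1, a chemokine receptor, also rose, by 4.54 and 4.24. Of these genes only Ctse was well above background on all 4 arrays, so the fitted sizes of the others are no bounds, and in the spleen Jhy was at least 101-fold and Klk1b24 at least 39.7-fold higher. Eps8l1 fell by 4.58 (SE 0.622, adjusted p 0.0397 in limma) and was at least 48.6-fold lower in spleen, where KO was not well above background, and Fcer2a, with a difference of -3.51, did not pass (SE 0.554, adjusted p 0.0777 in limma). Adjusted over the list alone, 14 of 17 neutrophil genes were higher in KO (Mmp8, S100a8 and Camp among them) and 7 of 11 MHC class II genes lower (H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb2, Cd74 and Ciita), against 0 of each over all genes. Lists of early B cell genes (3 higher, Bst1, Arpp21 and Tcf7l2; 1 lower, Sox4), myeloid transcription factors (4 higher) and B cell receptor signalling (3 lower, Cd79a, Blk and Cd22) had calls adjusted over the list alone, as did mature B cell genes (2 lower, Fcer2a and Cd22), with 0 over all genes. Also over the list alone, 4 Y-linked sex genes and the B-lineage factor Pou2f2 were lower. Cd9 and Cd36 of the marginal zone and B-1 list, Fosl2, Pdgfrb and Hdc were higher by the same adjustment. Of the members of the plasma cell list, Slpi was higher and Jchain lower by that adjustment, and the lists not mentioned had 0. On simulated data without any genotype effect the same fit called 6.15 genes on average and up to 44. A total of 10 adjusted calls lies within what these unchanged data gave. The 20 simulations drew noise independently for each gene, and the number of genes with a low unadjusted p was not compared. The fit has 1 residual degree of freedom, and its assumption of equal effects is not testable here. With cyclic loess it called 0 genes, with 2033 at an unadjusted p under 0.05. The number of calls depended strongly on the processing. Limma called 432 genes higher and 195 lower with normexp, 308 and 233 with an intensity trend and robust variance, and 2 and 0 with quantile normalization.

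**Figure D3:**
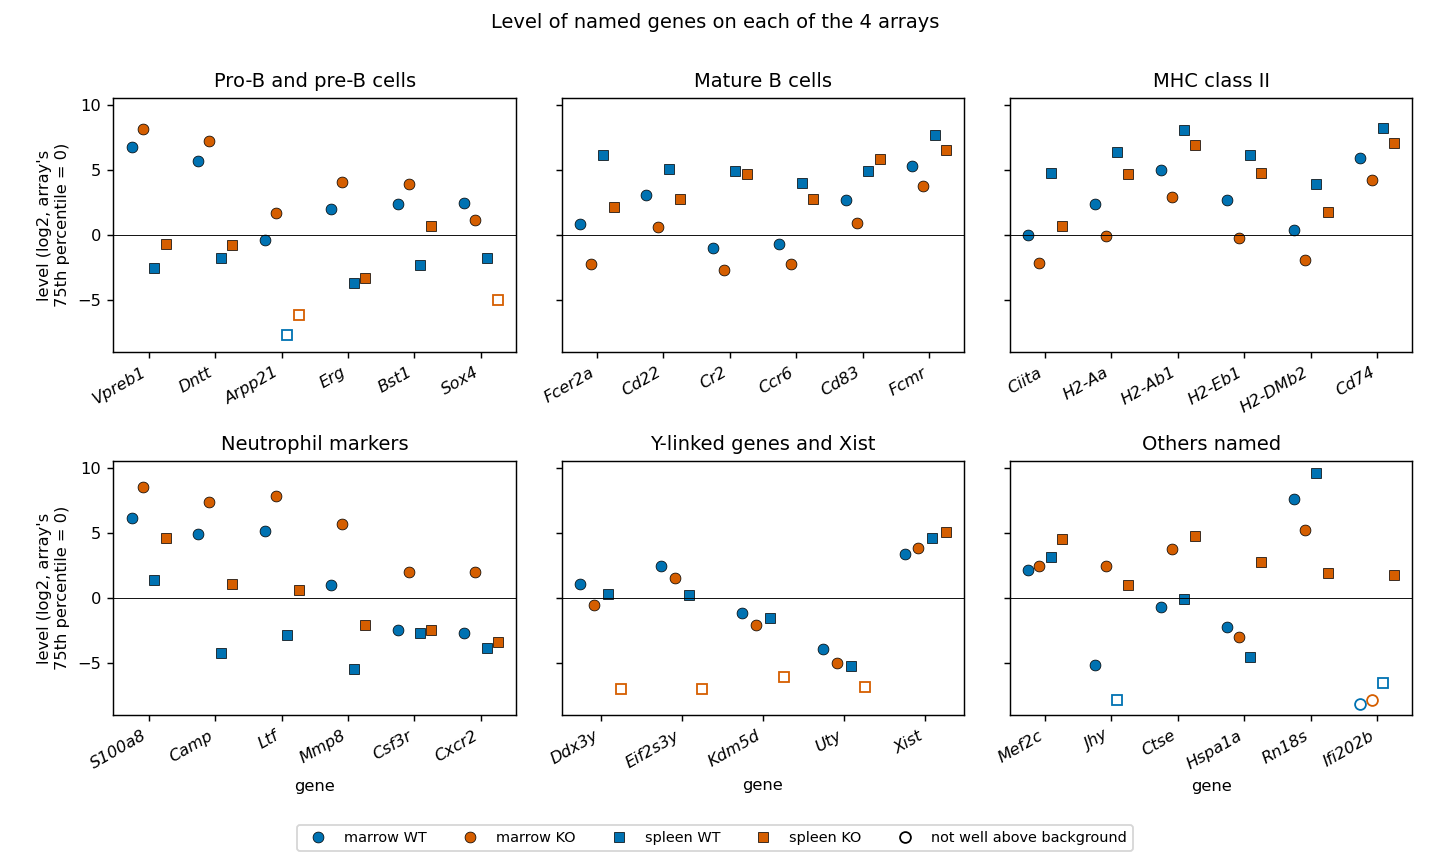
Levels (log2 signal relative to the array's 75th percentile, which is 0) of named genes, grouped by panel, with 1 symbol for each of the 4 arrays and open symbols for signals not well above background. Fcer2a stood at -2.20 on marrow KO, 0.85 on marrow WT, 2.19 on spleen KO and 6.16 on spleen WT, and Jhy at 2.48, -5.18, 1.01 and -7.87.

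The WT arrays of spleen and marrow gave the tissue difference beside which the genotype difference stands. Early B cell genes were far lower in spleen, in 20 of 23 cases, with a median of -4.72 (-4.23 with undetected members at their bound). Vpreb1 differed by -9.32, Rag1 by -9.29 and Dntt by -7.47, and Igll1, the other part of the surrogate light chain, was at least 673-fold lower. All 33 cell division genes were at least 2-fold lower in spleen, with a median of -3.20, such as Rrm2, a subunit of ribonucleotide reductase, at -4.71 and the cyclin Ccna2 at -4.64. All 11 MHC class II genes were higher in spleen (median 3.22; Ciita, 4.81), as were 19 of 32 mature B cell genes (median 1.30; Cr2, 5.91; Fcer2a, 5.30; 2 lower), 9 of 17 marginal zone and B-1 genes (median 1.04; Fcrl5, an Fc receptor-like protein, 5.52) and 25 of 28 interferon-induced genes (median 1.27; Cxcl10, a chemokine, 3.33). Bcl2, an inhibitor of apoptosis, was 2.37 higher and its relative Bcl2l1 differed by -3.32. Of the other cell types, neutrophil (median -4.02; Camp, -9.15), stromal (-1.86, or -1.81 with bounds), platelet (-2.47, or -2.46) and progenitor genes (-1.74, or -1.69) were lower in spleen, and NK cell (1.33), T cell (1.01) and macrophage genes (1.20) higher.

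In all, 3320 genes were at least 2-fold higher and 3376 lower in WT spleen among 21445 measured, and 3189 higher and 2823 lower in KO spleen against KO marrow among 20316. On the KO arrays these gene groups differed in the same directions: early B cell genes had a median of -4.44 (-4.10 with bounds), cell division genes -3.41, mature B cell genes 2.07 with 23 of 32 higher, MHC class II genes 3.38 and neutrophil genes -5.40. The 4 Y-linked genes were well above background on marrow KO and not on spleen KO, so the sex of the animals may also differ between these KO arrays. In limma over both genotypes, 626 genes were higher and 1188 lower in spleen at an adjusted p under 0.05. Rag1 (-9.14), Vpreb1 (-9.09) and the neutrophil granule gene Ngp (-8.26) had p-values among the smallest of lower genes, and Cr2 (6.64) and the metalloprotease Adamdec1 (7.29) had them among higher genes. Igll1 and Pdcd1lg2, a ligand of the inhibitory receptor PD-1, also passed. Igll1 was not well above background on either spleen array, nor Pdcd1lg2 on either marrow array. They have only bounds, at least 673-fold lower and at least 36.7-fold higher in WT spleen. Adjusted over the list alone, 33 of 33 cell division genes fell in spleen (28 over all genes), 20 of 23 early B cell genes fell (19 over all genes), 11 of 11 MHC class II genes rose (11 over all genes) and 17 of 17 neutrophil genes fell (15 over all genes). Marrow arrays were on 1 slide and scan and spleen arrays on another, so tissue and slide cannot be told apart. RNA integrity was not separated from tissue either. Of 3729 probe pairs along the same transcript, 23.6% differed by over 2-fold between the WT tissues and 15.6% between the KO tissues. The 3' probe minus the 5' probe had medians of -0.19 and 0.17.

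**Figure D4:**
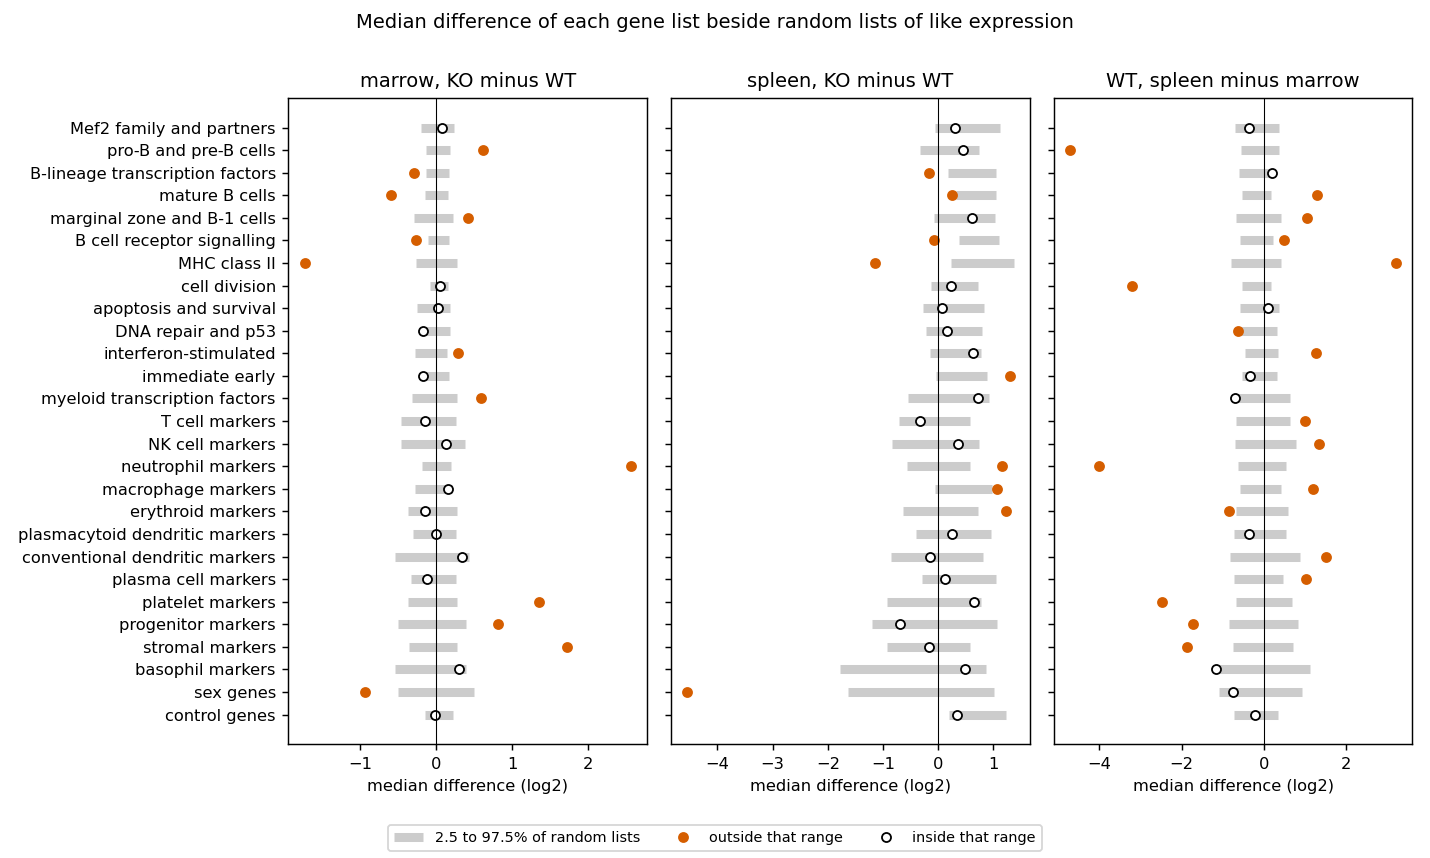
Median log2 difference of each fixed gene list (points) in marrow KO minus WT, spleen KO minus WT and WT spleen minus marrow, beside the range that holds 95% of random lists of like expression; filled points lie outside that range. MHC class II genes lie at -1.73, -1.14 and 3.22 and neutrophil genes at 2.56, 1.16 and -4.02.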

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

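The counts of neutrophil genes in both tissues, the gap between marker lists and the 4-fold threshold of the genes shared by both tissues were chosen as tests after the results were seen, and the other tests before.

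The first pattern is the higher neutrophil genes on both arrays labelled KO. Of the measured members 16 of 17 were at least 2-fold higher in marrow and 10 of 16 in spleen, with S100a8, one of the most abundant, at levels of 8.56 on marrow KO and 6.20 on marrow WT, and 4.62 on spleen KO and 1.43 on spleen WT. A lower share of B cells that raises every other cell type alike is argued against in the marrow, since the T cell, NK cell and erythroid medians lay at least 11.5 SD of random lists below the neutrophil median, although 5 of 15 T cell genes were at least 2-fold higher. That SD is a spread over genes, and stromal (1.73), platelet (1.35) and progenitor medians (0.82) did rise above the range of random lists. A lower B cell share with an uneven rise of other cell types therefore stays open. More neutrophil-lineage cells among the isolated cells is a candidate explanation that these counts leave open, and the rank of the signal added in the KO spleen beside that added in the KO marrow (Spearman rho 0.82 across 16 genes) decides nothing, since it followed the probes' brightness on marrow WT as closely (0.86). How far the isolation of B220 cells removed such cells is not known, since its method is not given. All 17 neutrophil genes were above background on marrow WT too, and no list member is in another list. Higher expression within B lineage cells was not tested.

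The second pattern is that 2.41 times as many genes were 2-fold apart in spleen as in marrow. In the brightest of 4 bins of genes the spleen count was 7.34 times the marrow count, so dim genes alone do not account for the excess. In that bin, however, the median gene differed by 0.75 in the spleen and by 0.05 in the marrow. A scaling offset of the dimmer spleen KO array could raise the count of bright genes, so that array stays open as a cause. The spleen WT array stays open too. Against the marrow array of the same genotype, 23.6% of probe pairs lay over 2-fold apart for spleen WT and 15.6% for spleen KO. The spike-in median was 443 on spleen WT and 1223 on spleen KO. Genes of the X and Y chromosomes made up 3.80% of the genes apart and 3.37% of those measured, a ratio of 1.13. This ratio cannot decide on a difference in sex between animals, which may also alter genes of other chromosomes. Y-linked genes were not above background on spleen KO, so sex stays open as a cause. Unequal RNA integrity is a candidate explanation that stays open, since 3' probes differed from 5' probes of the same transcript by a median of 0.53 in the spleen and 0.15 in the marrow. A larger effect of the genotype in the spleen also stays open, as untested.

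The third pattern is the 77 placed genes at least 4-fold apart the same way in both tissues, such as Jhy, Ctse, Fcer2a and Eps8l1, which also include neutrophil genes (S100a8, Mmp8, Camp, Ngp and Ltf) and the ribosomal RNA probes Rn18s and Rn28s1. If the knockout carried stretches of another strain's DNA, shared genes may lie near each other, and 33 lay 1 to 10 Mb from another, beside a median of 34 and an upper limit of 44 in the central 95% of random draws. Within 20 Mb of Mef2c lay 2 of them, beside a median of 1 and an upper limit of 3. Neither count separates these cases, so strain DNA and an effect of the genotype both stay open with 1 array per group. A different mix of cells or of RNA and the position of an array on its slide, which followed the genotype in both tissues, stay open as well. So does the sex of the animals. Y-linked genes differed by -0.87 (Eif2s3y) to -1.59 (Ddx3y) in the marrow and were not above background on spleen KO.

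Named genes whose KO minus WT difference was over 2-fold in opposite directions in marrow and spleen are given as values, and their difference between tissues was not tested. Alas2 differed by -1.13 in marrow and 1.55 in spleen. Cd163, a scavenger receptor of macrophages, differed by -1.26 and 2.46. Cd247, a chain of the T cell receptor complex, differed by 1.14 and -1.19. Dcn, the matrix protein decorin, differed by 2.07 and by at most -1.82, a bound. Mmp9, a gelatinase, differed by 3.99 and by at most -1.49, a bound. Oas3, an interferon-induced synthetase, differed by 2.48 and -1.999. Rgs1 differed by -1.80 and 4.77. Sparc, a matrix glycoprotein, differed by 1.68 and -1.85.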

How the results depend on the processing

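Cyclic loess, leaving out genes whose probes differ over 2-fold and leaving out the spleen KO array were chosen after the data were seen, and the other alternatives before. Of the counts and main values under an alternative, 122 stayed within 1.5 times (for values, within their spread) of those reported and 59 did not. Of the 122, 17 came from the series matrix values, which could not differ. Another 4 came from leaving out the spleen KO array, where little change was possible. Of list medians 627 moved by no more than the SD of random lists, 81 of them from the identical series matrix values, and 100 moved by more. Another 2, outside the range of random lists on the side of their own sign, reversed. Signs of list medians changed in 39 cases, over 20 medians, where the reported median lay inside the range of random lists, and in 4 cases, over 3 medians (B cell receptor signalling, sex and mature B cell genes in spleen), where it lay outside. Of named genes 537 stayed within the spot SD, 257 moved and 2 changed sign. Of the 537, 90 each came from the series matrix values, no filter and genes above background on both arrays. Another 76 came from leaving out genes whose probes differ, and none of these settings could alter a named gene's value. Moved and stayed were 66 and 24 with normexp, 60 and 30 with quantile normalization and 63 and 27 with cyclic loess. They were 36 and 54 with scaling by a median, and 32 and 56 with the median over a gene's probes. The cause of these shifts was not tested, except that thresholds, filters and the adjusted p alter what is counted. Of the gene spots on spleen KO 59.3% were well above background, and genes not above it have only a bound there.

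With normexp, 1037 genes were higher and 342 lower in KO marrow (1771 and 1040 as reported), 1383 lower in KO spleen (2863), 2073 higher and 2219 lower in WT spleen against WT marrow (3320 and 3376), 1750 lower in KO spleen against KO marrow (2823), and 271 and 153 shared by both tissues (441 and 386). Mef2c in spleen differed by 1.26 (1.37), and limma called 432 genes higher and 195 lower in KO (8 and 2) and 1122 higher in spleen (626). With quantile normalization Mef2c in spleen differed by 0.67 and limma called 2 and 0 genes in KO. Scaled by the median of probes above background, Mef2c in spleen differed by 1.47, limma called 44 and 14 genes in KO, and the B cell receptor signalling median in spleen became 0.025 from -0.07. With cyclic loess Mef2c in spleen differed by 0.77, and limma called 0 and 0 genes in KO and 261 and 686 in spleen against marrow (626 and 1188). The median of all genes in KO spleen against KO marrow, 0.19, was 0.34 with normexp and 0.08 with cyclic loess, and was within 0.1 of its reported value in the other comparisons under each scaling.

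With genes above background on both arrays only, the sex gene median in spleen became 0.41 from -4.54 (-3.43 with bounds), since only Xist was left, and with genes above background on all arrays limma called 283 and 163 genes in KO. Without a filter, 2123 genes were lower in KO marrow, 5046 higher in KO spleen against KO marrow, 699 shared lower, the correlation between tissues was 0.24 (0.34), and limma called 326 and 264 genes in KO and 1150 higher in spleen. With the median over a gene's probes, Fbxo2 in spleen became 0.35 from -4.04 and St6galnac2 -2.32 from 3.10, and Mef2c 0.38.

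At 1.5-fold, 2977 genes were higher and 3142 lower in KO marrow, 6517 and 4443 in KO spleen, 5281 and 6030 in WT spleen against marrow, 5570 and 4282 in KO spleen against marrow, and 1077 and 1303 were shared. At 3-fold these counts were 929 and 256, 1494 and 1322, 1680 and 1634, 1431 and 1674, and 122 and 64. With an intensity trend and robust variance limma called 308 and 233 genes in KO and 1088 higher in spleen, and at an adjusted p under 0.1 it called 41 and 15 in KO and 1124 higher in spleen.

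Leaving out genes whose probes differ over 2-fold gave 1619 and 993 genes in KO marrow and 3045 and 2628 in KO spleen. Without the spleen KO array, and with the brightest probe chosen over the other arrays, 1773 genes were higher and 1047 lower in KO marrow and 3319 and 3374 in WT spleen against WT marrow. Neither comparison uses that array otherwise, so little change was possible. The series matrix values were identical to the scanner values and test nothing. A fit with the slide as a block was not run, since slide and tissue coincide. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers, apart from the comparison of KO with WT within each tissue that limma's tissue term already makes.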

Other observations

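The test of a smaller share of mature B cells was chosen after the lower mature B cell and MHC class II genes were seen.

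Further members of the fixed lists with large differences between spleen KO and WT are given here. Among mature B cell and marginal zone genes, the sphingosine 1-phosphate receptor S1pr3 differed by -1.87 and its relative S1pr4 by -1.90, while the chemokine receptor Cxcr4 was 1.64 higher. Among marginal zone genes the lipid-presenting molecule Cd1d1 was 2.24 and the scavenger receptor Cd36 2.21 higher, and Fcrl5 differed by -2.27. Among NK cell markers Prf1, perforin, and Nkg7 differed by -2.59 and -2.06. Of the apoptosis genes Pmaip1 (Noxa) was 2.68 higher and Bcl2l1 differed by -1.92. Further list medians in spleen KO against WT were 0.73 for myeloid transcription factors (Cebpb, 3.05), 0.25 for plasmacytoid dendritic cell, 0.65 for platelet and 0.48 for basophil genes. Those of conventional dendritic cell (-0.16, with a mean of 0.22), progenitor (-0.70) and stromal genes (-0.17) changed sign with normexp.

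In WT spleen against WT marrow, Jchain was 5.57 higher, Ly6a (Sca-1) 5.66 and the activation-induced apolipoprotein Apol7c 6.67. Plasma cell genes had a median of 1.02 with 6 of 12 higher and conventional dendritic cell genes one of 1.52. Within the range of random lists were B-lineage transcription factors (0.19), apoptosis (0.10), immediate early (-0.33), plasmacytoid dendritic cell (-0.36) and basophil genes (-1.17, or -0.80 with bounds). The B cell adaptor Bank1 was 2.90 higher in spleen.

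A smaller share of mature B cells among the B220 cells of the KO marrow is a candidate explanation for its lower mature B cell and MHC class II genes. It predicts that genes higher in spleen than in marrow on the WT arrays would be lower on the KO marrow array, and over 43 members of both lists these differences had a Spearman rho of -0.54 across genes, and the marrow WT array that both share would by itself push rho toward positive values. Within the lists rho was -0.28 for mature B cell genes and -0.60 for class II genes. Of 19 mature B cell genes at least 2-fold higher in WT spleen 8 were at least 2-fold lower in KO marrow, and of 11 class II genes 9 were. The class II genes were also lower in the spleen, by a median of -1.14, which a shift in marrow composition alone would not cover. Signs of RNA composition moved with that spleen comparison, where 43.2% of probe pairs along a transcript differed by over 2-fold, so this value is uncertain.

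Levels of Xist, the RNA of the inactive X chromosome, were 3.84 on marrow KO, 3.36 on marrow WT, 5.05 on spleen KO and 4.64 on spleen WT, above background on all 4 arrays. The 4 Y-linked genes were above background on 3 arrays and not on spleen KO. Ifi202b stood at 1.76 on spleen KO and was not well above background on the other arrays. Rn18s stood at 5.22 on marrow KO, 7.65 on marrow WT, 1.93 on spleen KO and 9.64 on spleen WT.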
